A study of Drosophila melanogaster with 6 samples.

How the data were processed

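Replication timing was measured in Kc cells, a female line derived from Drosophila melanogaster embryos. Per the labels' protocols, growing cells were exposed to 50 µg/ml of the thymidine analogue BrdU for 1 hour, fixed in ethanol, stained for DNA content with propidium iodide and sorted into an early, a middle and a late fraction of S phase. BrdU-labelled DNA was then recovered with an anti-BrdU antibody, sheared and made into Illumina libraries. Signal of a window in a fraction is therefore read here as label taken up in cells of that DNA content. There were 6 libraries, 2 replicates of each of the 3 fractions, called Early S, Mid S and Late S here. For Mid S replicate 1 the fraction was taken from the title, since its source label leaves it out. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

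The authors deposited 1 file per library and 3 combined files, each with 1 value per window in RPKM (reads scaled to window length and library size), per the file headers. Windows were 10 kb wide and started every 2.5 kb, so neighbouring windows share reads. Each file held 55900 windows on 14 sequences. The last window of each sequence was shorter than 10 kb. The aligner, the genome build, the read filters and any correction for input DNA are not given in the sources used here. The sequence names (2LHet, XHet, U and others) are of the type used in Release 5 of the genome, and coordinates are given as in the files, counted from 1. The gene table at hand is of Release 6, so no gene positions were used, and results that need gene positions or GC content (gene lists, gene density, GC correction) were not run. Reads from repeated sequence that align to several places can be lost or spread by an aligner, which matters most for the pericentric scaffolds and U.

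Every value in windows of full width was a whole multiple of the value of 1 read, within 0.02 reads, in 100% of values. This gave the number of reads behind each library: 2936097 and 1892986 for Early S replicates 1 and 2, 2801800 and 1981524 for Mid S, and 1856781 and 1384200 for Late S. The median window held 94 to 213 reads per library. A count of 0 allows up to 3 reads, which is 0.102 RPKM in the deepest library and 0.217 RPKM in the shallowest. Such limits cover counting error only. The combined files equalled the read-weighted mean of the 2 replicates to within 9.95e-14 RPKM and served as an alternative for the chromosome arms only.

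From these values, windows at 0 in all 6 libraries (2466) were left out and 53434 were tested. Values were put on the log2(RPKM + pseudocount) scale with a pseudocount of 0.0341 RPKM, the lowest value above 0 in the 6 libraries, so fold changes of windows with few reads are understated. limma 3.58.1 in R 4.3.3 fitted the means of the 3 fractions to all 6 libraries (lmFit, eBayes with trend), with 3 residual and 10.7 prior degrees of freedom. Tests were two-sided, and windows are called past a Benjamini-Hochberg adjusted p of 0.05. The fit was tested on simulated data for Early S against Late S, with 200 of 53434 windows changed. It recovered 1.5% of the changes of 0.5, 62.7% of those of 1 and 95.5% of those of 2 on the log2 scale, with 2 calls among unchanged windows. With so few changed windows the adjusted threshold is stricter than in the data, where most windows were called. These shares therefore do not give the recovery in the data, where the smallest called difference of Early S against Late S was 0.332. The simulated noise was counting error plus 0.5 times a median replicate SD, equal in all fractions and independent between windows. In the data neighbouring windows share reads and Late S varied most between replicates. The 2 calls therefore do not give the rate of false calls in the data. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

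The fraction with the highest mean was taken on the linear scale and called only where it passed the test against both others. For each arm or scaffold with at least 20 tested windows, the median of each library minus that library's median over all tested windows was compared with the order early, mid, late in an exact two-sided permutation test over the 90 arrangements of the libraries, whose smallest p is 0.0222, with Benjamini-Hochberg adjustment over 12 sequences. Blocks were runs of called windows of the same sign with a log2 difference of at least 1 (0.5 in the comparisons with Mid S), joined over gaps of at most 2 windows. The block caller recovered its simulated runs. These were unbroken and no other simulated window could be called, so this checked the code only. The text may name the 5 longest blocks and the 5 with the largest mean difference in each direction, of at least 5 windows, on X, 2L, 2R, 3L, 3R and 4, and every arm or scaffold with at least 20 windows. These rules, the tests and most alternatives were fixed before the data were examined. Autocorrelation was taken across windows by distance on the 5 long arms. Alternatives covered the pseudocount, a filter on low values, centring and quantile normalization, a replicate block, the set of libraries and windows, block thresholds and leaving out each library. Precision weights from limma's voom on the recovered reads, uncentred arm values and the replicate block for the highest fraction were added after seeing the data.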

Results

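Label uptake was compared between Early S, Mid S and Late S cells along the genome of Kc cells, with 2 libraries per fraction of 1384200 to 2936097 reads each. The design asks which parts of the genome replicate early and which late. Median window values were 5.96 and 5.71 RPKM in the Early S libraries, 7.60 and 7.52 in Mid S, and 6.36 and 6.79 in Late S. Between 5.72% and 7.47% of windows were at 0 in a library. The sequences most often without reads were YHet, with 88.5% of windows at 0 in all libraries, and U, the collection of unplaced sequence, with 36.1%.

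Each fraction resembled its own replicate more than any other fraction. Across windows, which are not independent of each other, Pearson's r of log2 values between replicates was 0.981 in Early S, 0.974 in Mid S and 0.948 in Late S. Early S and Late S libraries were the least alike, with r from 0.486 to 0.587 and Spearman's rho from -0.192 to -0.0888. The positive sign of this r was not kept under other settings. On linear values r ran from -0.276 to -0.130. With the filter on low values r ran from -0.512 to -0.387 and rho from -0.599 to -0.469. Early S against Mid S gave r from 0.871 to 0.893, and Mid S against Late S from 0.790 to 0.844. With the filter these ranges were 0.600 to 0.639 and 0.208 to 0.335. Late S replicate 2 lay nearer to each Early S and Mid S library than Late S replicate 1 did. Replicates differed by more than sampling noise in each fraction, with a chi-square per degree of freedom of 2.15 in Early S, 2.39 in Mid S and 3.23 in Late S, so both libraries of each fraction were kept as separate samples. This does not tell separate cultures from repeat preparations of one.

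Regions with more label in Early S and regions with more label in Late S alternated along the long arms X, 2L, 2R, 3L and 3R, while the small chromosome 4 had more label in Early S along most of its length. On chromosome 4, 80.2% of windows were called higher in Early S and 3.31% higher in Late S. On 2R, 48.5% of windows were higher in Early S and 31.1% in Late S, and on 2L the order turned, with 37.3% and 47.7%. The scaffolds of pericentric heterochromatin had more label in Late S. On 3RHet, 83.2% of windows were higher in Late S and 0.891% in Early S, and on the shorter XHet 90.8% of 65 windows were higher in Late S. The Late S shares were lower on 2LHet (74.8%), 3LHet (68.1%) and 2RHet (56.8%), where 10.1%, 10.3% and 8.24% of windows were higher in Early S. Over all tested windows, 37.6% (20097) were higher in Early S and 44.2% (23605) in Late S (called by limma). The excess of Late S calls was not kept under every setting: the order turned after quantile normalization, with shares of 38.2% and 37.9%. On X, 2L, 2R, 3L, 3R and 4 alone it shrank, with shares of 41.7% and 42.1%. The median difference over all windows was -0.23 on the log2 scale, and differences near 0 are to be read relative to it. The remaining 18.2% of windows were not called, and their differences were not detectable at this depth and number of libraries.

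**Figure D1:**
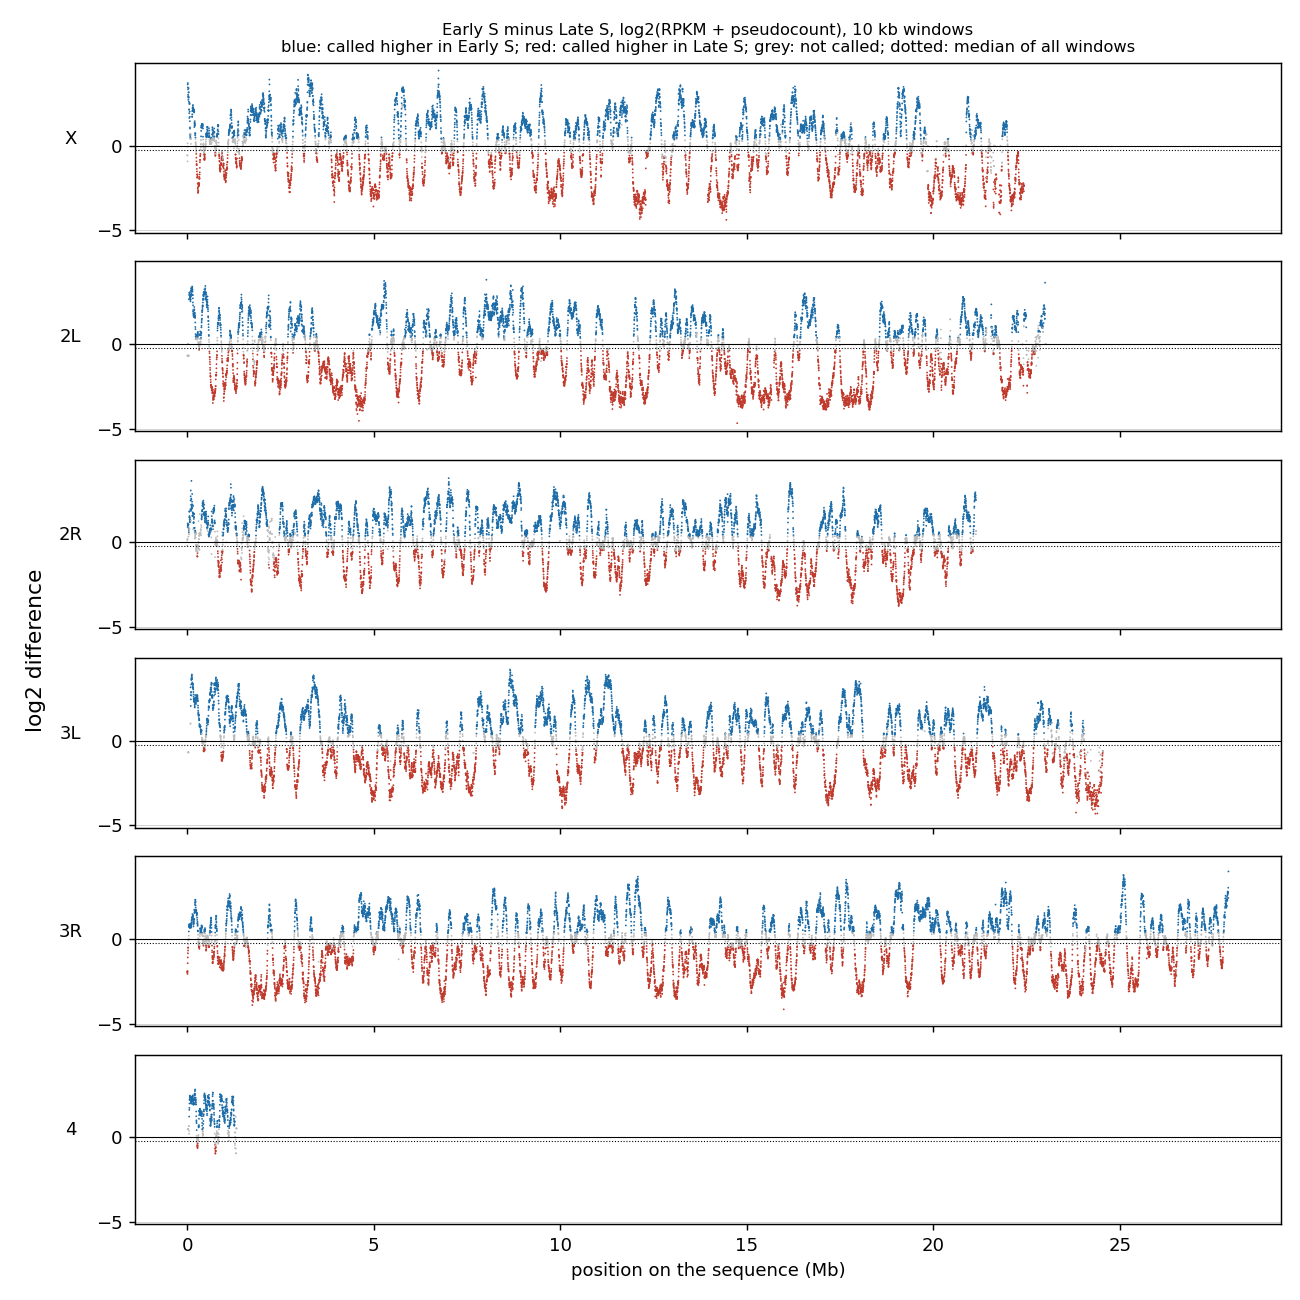
Early S minus Late S difference on the log2(RPKM + pseudocount) scale (y axis) of each 10 kb window against its position in Mb (x axis) on X, 2L, 2R, 3L, 3R and 4, each point the difference of the means of 2 libraries per fraction, coloured by its call. Early (blue) and late (red) stretches alternate on the long arms, chromosome 4 has 80.2% of its windows called higher in Early S, and the dotted line marks the median of all windows, -0.23.

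Early and late windows were gathered in blocks of many neighbouring windows. The longest late block covered 620 kb of 2L, from 17495001 to 18115000, where the value was 16.3 ± 0.450 RPKM in Late S, 5.56 ± 0.501 in Mid S and 2.19 ± 0.271 in Early S (SD, n = 2), a mean log2 difference of -2.99. The longest early block covered 525 kb of 2R, from 8442501 to 8967500, with 20.2 ± 0.505 RPKM in Early S, 10.6 ± 0.108 in Mid S and 4.77 ± 1.01 in Late S, a mean log2 difference of 2.07. Every window of these 2 blocks was called, with adjusted p of at most 0.000168 on 2L and 0.00483 on 2R (limma). Blocks are built from called windows, so these calls are no separate evidence for them. On X, 2L, 2R, 3L, 3R and 4 together there were 433 early blocks covering 38.9 Mb and 379 late blocks covering 41.3 Mb. Their median lengths were 60 kb and 82.5 kb.

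Other long late blocks lay on 2L at 11287501 to 11802500 (mean log2 difference -2.78) and at 14535001 to 15015000 (-2.61), on 3R at 1660001 to 2155000 (-2.85) and on 3L at 18122501 to 18587500 (-2.29). A late block near the centromeric end of 3L, at 24095001 to 24450000, had a mean difference of -3.15, the largest among late blocks at the pseudocount used, with 5.32 ± 0.297 RPKM in Late S and 0.547 ± 0.0550 in Early S (SD, n = 2). On X, the block at 11927501 to 12297500 had a mean difference of -3.12 and the block at 14172501 to 14535000 one of -3.03. The order of these blocks depends on the settings: with 10 times the pseudocount the 3L block was at -2.39, X 14172501 to 14535000 at -2.82 and 2L 17495001 to 18115000 at -2.79, and after quantile normalization the 3L block was at -2.20 and X 14172501 to 14535000 at -2.44. A short block of 22.5 kb on X at 21600001 to 21622500 had -3.14, but its Early S value of 0.0778 ± 0.0104 RPKM lay below the 3-read limit of each Early S library. Its difference was -1.62 with 10 times the pseudocount, -3.98 with the smaller pseudocount tried and -1.64 after quantile normalization.

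Other long early blocks lay on 3L at 8437501 to 8882500 (mean log2 difference 2.29), on 3R at 19475001 to 19917500 (1.68), on X at 1682501 to 2107500 (2.00) and on 2R at 3305001 to 3722500 (2.05). The largest mean early difference, 2.88, lay on X at 3175001 to 3422500, with 12 ± 1.60 RPKM in Early S and 1.82 ± 0.556 in Late S (SD, n = 2). It was followed by 2R at 16095001 to 16242500 (2.72), X at 5770001 to 5865000 (2.72), and 3L at 3292501 to 3560000 (2.64) and at 17827501 to 18100000 (2.60). This order also depends on the settings. After quantile normalization the 3L block from 17827501 was at 2.73, the 2R block from 16095001 at 2.72 and the 3L block from 3292501 at 2.49. On 3L the early block at 17827501 to 18100000 and the late block from 18122501 lie next to each other. By arm, early blocks covered 38.1% of 2R and 26.5% of 3R, and late blocks covered 41.1% of 2L and 23.7% of 2R. Chromosome 4 had 7 early blocks covering 69% of its length and no late block. At a log2 difference of at least 2 in place of 1, the total fell to 15.2 Mb in early and 22.8 Mb in late blocks.

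**Figure D2:**
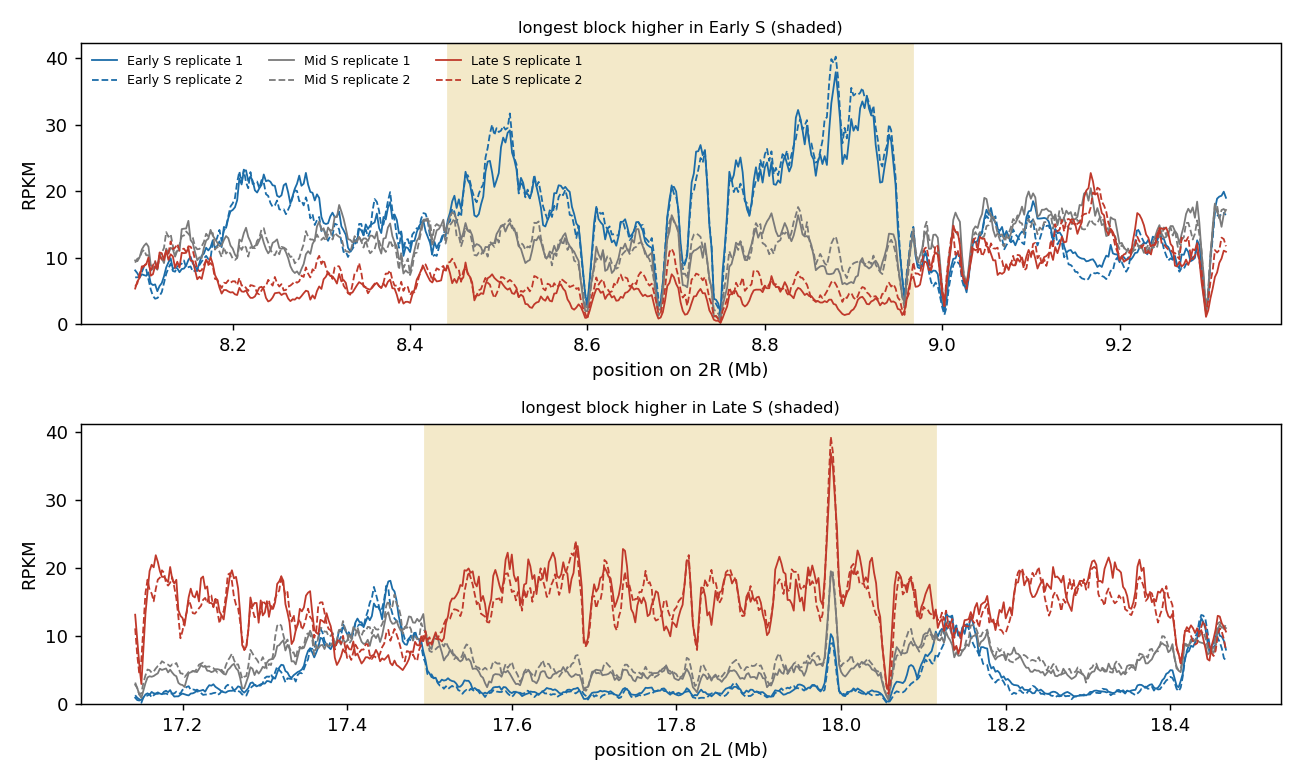
RPKM (y axis) of each of the 6 libraries against position in Mb (x axis) around the longest early block on 2R (top) and the longest late block on 2L (bottom), with replicate 1 solid, replicate 2 dashed and the block shaded. Early S lies highest within the 2R block (mean 20.2 RPKM) and Late S highest within the 2L block (mean 16.3 RPKM), with Mid S between in both.

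Mid S was compared with Early S to separate windows that replicate first from those that follow. Early S exceeded Mid S most in blocks on X at 3207501 to 3387500, with 13.4 ± 2.05 against 3.23 ± 0.162 RPKM (SD, n = 2), and on 3L at 11157501 to 11390000, with 19.2 ± 1.86 against 4.97 ± 0.378. The mean log2 differences of these blocks were 2.15 and 2.01. Mid S exceeded Early S over the longest stretch on 2L, at 17487501 to 18115000, with 5.62 ± 0.489 against 2.24 ± 0.273 RPKM, a mean log2 difference of -1.39 that was -0.44 after quantile normalization. Late S was higher still in that stretch, at 16.2 ± 0.439 RPKM. Of all tested windows, 20.5% (10938) were higher in Early S and 43.5% (23221) in Mid S, so 32.0% of the calls were higher in Early S. After quantile normalization 18.3% of windows were higher in Early S and 24.4% in Mid S, which put 42.9% of the calls in Early S. With libraries centred on their medians, which by construction evens out the directions, 49.1% of the calls were in Early S. The share of tested windows higher in Early S, 20.5%, fell when any Early S or Mid S library was left out, which leaves 1 library in that fraction.

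Mid S was compared with Late S to separate middle from late replication. Mid S exceeded Late S over the longest stretches on 2R at 8157501 to 8992500, with 11.2 ± 0.0343 against 5.36 ± 0.957 RPKM (SD, n = 2), and on X at 1565001 to 2300000, with 6.63 ± 0.523 against 3.17 ± 0.219. The mean log2 differences were 1.10 in both. Early S was higher still in both, at 18.4 ± 0.170 and 10.6 ± 0.264 RPKM, so these stretches were not highest in Mid S. Late S exceeded Mid S over the longest stretch on 2L at 17515001 to 18112500, with 16.5 ± 0.473 against 5.44 ± 0.530 RPKM, a mean log2 difference of -1.64. Of all tested windows, 38.7% (20677) were higher in Mid S and 26.9% (14374) in Late S. After quantile normalization the shares were 38% and 28.7%. With libraries centred on their medians, which by construction evens out the directions, they were 32.1% and 32.3%. Both shares as first given fell whichever library was left out, and leaving out a Mid S or Late S library leaves 1 in that fraction.

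The genome was divided by the fraction with the highest mean. Late S was highest in 43.2% of windows, Early S in 34.9% and Mid S in 21.9%. With libraries centred on their medians these shares were 47.2%, 43.8% and 9.08%. Chromosome 4 stood apart, with Early S highest in 72.4% of windows, Mid S in 25.5% and Late S in 2.14%. Late S was highest in 96.9% of windows on XHet, 90% on 3RHet, 83.2% on 2LHet, 78.6% on 3LHet and 71.55% on 2RHet. Called against both other fractions, Late S was highest in 14247 windows (26.7%), Early S in 10878 (20.4%) and Mid S in 1300 (2.43%). Mid S windows called above both others held 11.1 ± 0.267 RPKM in Mid S, 7.44 ± 0.363 in Early S and 7.46 ± 0.121 in Late S (SD of library medians, n = 2), and made up 6.23% of chromosome 4, 3.57% of 2R and 3.32% of 3R. The called Mid S share depended on the scaling. It was 0.13% with libraries centred on their medians, which lowers Mid S because its medians were the highest, and 6.03% after quantile normalization. It fell when any Early S or Mid S library was left out, which leaves 1 library in that fraction. The share with the highest mean in Mid S, which needs no test, stayed between 21.0% and 22.9% whichever library was left out. The called Early S share was 30.6% with centring and fell when any Early S or Mid S library was left out. The called Late S share fell whichever library was left out.

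Chromosome 4, a small chromosome rich in repeats, had the highest Early S minus Late S difference of the 12 sequences, and the pericentric scaffolds had more label in Late S than in Early S. Relative to each library's median, chromosome 4 was 1.65 ± 0.396 higher in Early S than in Late S on the log2 scale (error from the SDs of both fractions, n = 2 each), or 3.13-fold. The scaffolds were higher in Late S, with Early S minus Late S of -2.84 ± 0.265 on 3RHet, -2.42 ± 0.0780 on 2LHet, -2.12 ± 0.294 on XHet, -1.68 ± 0.0661 on 2RHet and -1.58 ± 0.129 on 3LHet. Their sizes depend on the windows used: with only windows above the 10th percentile of mean signal, the difference was -0.78 on 2LHet, and with means in place of medians -1.73, with the same direction and call. Among the long arms, 2R (0.45 ± 0.0135) and X (0.19 ± 0.0234) lay on the Early S side of the library medians and 2L (-0.25 ± 0.0542) on the Late S side. These 9 sequences each had an exact permutation p of 0.0222, the smallest possible, and an adjusted p of 0.0296 over 12 sequences. In each of the 12 sequences, both Early S libraries lay on the same side of both Late S libraries. The test also orders the Mid S libraries. The order early, mid, late did not pass on 3L (difference 0.04 ± 0.0225) or 3R (-0.06 ± 0.0494), with adjusted p of 0.356 and 0.267 in the exact permutation test. On both, the Mid S mean lay below the means of Early S and Late S. Nor did this order pass on U (-1.71 ± 0.200, adjusted p 0.0800, exact permutation), where the Mid S libraries overlapped those of Early S. The median Early S value on U was 0.0605 RPKM and lay below the 3-read limit. The calls of 2R and X rest on the centring: without it the differences were 0.30 (adjusted p 0.160, exact permutation) and 0.05 (adjusted p 0.622, exact permutation). With means over windows in place of medians X was at 0.089 (adjusted p 0.0970, exact permutation), 3R at -0.13 and U at -1.70, the last 2 with an adjusted p of 0.0267 (exact permutation). With only windows above the 10th percentile of mean signal, 3R (-0.11) and U (-2.87) also passed, both with an adjusted p of 0.0242 (exact permutation), and without centring U passed at -1.85 (adjusted p 0.0333, exact permutation).

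**Figure D3:**
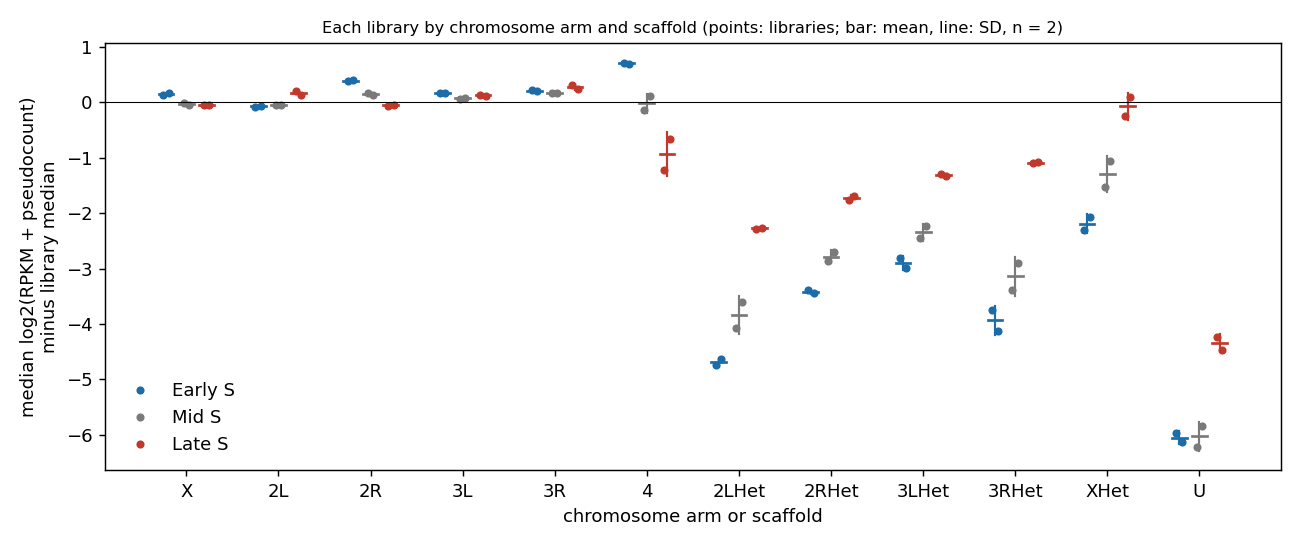
Median log2(RPKM + pseudocount) minus the library's median over all tested windows (y axis) for each chromosome arm or scaffold (x axis), with points for the libraries, bars for the mean and lines for the SD (n = 2) of Early S, Mid S and Late S. Chromosome 4 falls from Early S to Late S (difference 1.65), while the pericentric scaffolds rise, most on 3RHet (difference -2.84).

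Neighbouring regions were alike in timing on X, 2L, 2R, 3L and 3R. The autocorrelation of the Early S minus Late S difference across windows fell below 0.5 at 80 kb, for the means and for each replicate number alone. It fell below 0.1 at 320 kb for the means. Windows less than 10 kb apart share reads and were not used for this.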

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

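The tests on the Late S replicates and on 2RHet alone were chosen only after the result was seen. Of the sequences left out of the comparison of arms for too few windows, M, the mitochondrial sequence, held 241 reads over its 2 non-overlapping windows and all libraries, with 12 to 93 reads per library, above the 3 reads that a count of 0 allows. Its values were 0.745 ± 0.0666 RPKM in Early S, 0.650 ± 0.616 in Mid S and 1.98 ± 1.96 in Late S (SD, n = 2). YHet, a scaffold of the Y chromosome that female cells lack, held 9 reads over 35 non-overlapping windows and all libraries, with 0 to 3 reads per library, so no single library passed that limit and only the sum did.

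On 2LHet, 2RHet, 3LHet, 3RHet and XHet the median Early S minus Late S difference was -1.99 on the log2 scale. Low signal in repeated sequence would make equally weak windows of the long arms look as late, but arm windows matched on total signal had a median of -0.45, although on 2RHet alone (-1.40, against -0.53 in matched windows) the gap was too small to decide. The pseudocount understates the differences of windows with few reads, so it could not make these scaffolds look late. A test on well covered windows therefore decides nothing here. Pericentric windows with a mean of at least 20 reads had a median of -2.17. Late replication of these scaffolds stays open as a hypothesis. GC content and the handling of reads that align to several places stay open beside it, since neither was tested.

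Across windows of X, 2L, 2R, 3L, 3R and 4 the Late S replicates differed more than those of the other fractions. The median of chromosome 4 relative to the library was -1.22 in Late S replicate 1 and -0.66 in replicate 2. On 2LHet, 3LHet and 3RHet the SD of these medians was lower in Late S (0.0110, 0.0137 and 0.0120) than in Early S (0.0773, 0.128 and 0.265). On 2RHet and XHet it was higher in Late S (0.0525 and 0.239) than in Early S (0.0402 and 0.171). Lower depth alone would end the larger Late S difference on the arms after all libraries are thinned to 1384200 reads. As deposited, the SD of the log2 difference between replicates was 0.398 in Late S, 0.285 in Early S and 0.276 in Mid S. After thinning, with a larger pseudocount, these SDs were 0.395, 0.320 and 0.299, so the gap narrowed but did not close. The Late S value was still 1.23 times that of Early S and 1.32 times that of Mid S. In the tenth of windows with the highest Early S values, Late S replicate 2 exceeded replicate 1 in 87.7%, with medians of 5.13 and 3.82 RPKM, as label from earlier cells in replicate 2 would give. Unlabelled DNA or a shifted sorting gate could give the same and was not tested. No biological explanation was tested, since the labels give no difference between the replicates.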

How the results depend on the processing

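The voom weights, the uncentred arm values and the replicate block for the highest fraction were chosen after seeing the data. Early S against Late S stayed within 1.5 times in both directions under each alternative run (34 values), though the order of its shares turned after quantile normalization (38.2% higher in Early S, 37.9% in Late S), and so did 27 of 34 values for Early S against Mid S and 30 of 34 for Mid S against Late S. Centring moved the share higher in Early S than in Mid S from 20.5% to 31.2% (16646 windows), the called Early S and Mid S shares to 30.6% and 0.13%, and the highest mean in Mid S to 9.08%. Quantile normalization moved the share higher in Mid S than in Early S from 43.5% to 24.4% (13034 windows) and the called Mid S share to 6.03%. Centring evens out the directions by construction, and for quantile normalization the cause was not tested. A log2 difference of at least 1 left 7.58% higher in Early S and 25.8% in Mid S, and 15.5% in Mid S and 15.3% in Late S for the last pair, and of 2 left 15.2 Mb of early and 22.8 Mb of late blocks. Non-overlapping windows gave 5017 and 5917 calls for Early S against Late S, 2722 and 5771 for Early S against Mid S, and 5163 and 3594 for Mid S against Late S, because only 13365 windows were tested. With a library left out, which assumes that the lone one varies like the others, the ranges were 12% to 22.7% (higher in Early S than Mid S), 25.2% to 37.6% (Mid S than Late S), 17.4% to 26.1% (Late S than Mid S), and 11.9% to 22.4%, 0.35% to 2.96% and 17.3% to 25.7% for windows called highest in Early S, Mid S and Late S. For the arms these ranges were 0.18 to 0.21 on X, -0.29 to -0.21 on 2L, 0.44 to 0.45 on 2R, 1.37 to 1.93 on 4, -2.47 to -2.36 on 2LHet, -1.72 to -1.65 on 2RHet, -1.67 to -1.49 on 3LHet, -3.03 to -2.65 on 3RHet and -2.29 to -1.95 on XHet. Without a Mid S library the smallest permutation p is 0.0667, so no arm could pass there. Means over windows brought 3R (-0.13) and U (-1.70) past the threshold and X (0.089) below it, and the filter on low values brought 3R (-0.11) and U (-2.87) past it. The filter also gave -0.78 on 2LHet and -1.17 on 2RHet, and the authors' combined files -2.74 on 2LHet and -2.05 on U. Without centring 2R (0.30) and X (0.05) no longer passed, U (-1.85) passed and 3L was at -0.10, since the same offset between library medians enters every sequence. For the means, the filter and the combined files the cause was not tested. Pearson's r between the Mid S replicates was 0.939 on linear values and 0.923 with the filter. Between Early S and Late S libraries, r turned from positive to negative under both of these settings. Deviations of equal replicate numbers were nearly uncorrelated between Early S and Mid S (r -0.0101) and between Early S and Late S (0.0325). They were weakly correlated between Mid S and Late S (0.212). With the replicate block the calls were 38.0% and 44.5%, 21.3% and 44.2%, and 39.6% and 27.7% for the 3 pairs in the order above. Weights from voom gave 37.9% and 44.7%, 23.3% and 45.2%, and 39.5% and 29.8%. Of 399 values for the blocks named in the 3 comparisons, 35 moved by more than the spread between replicates and none changed sign. Several alternatives could not change these values, such as the replicate block, the arms alone or leaving out a library of the fraction not compared. GC, gene list and gene density alternatives were not run. Depth limits windows with few reads, such as those on U.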

Other observations

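The ends of the long arms differed in timing. The last 1 Mb of X and of 3L, next to the centromere, had more label in Late S, with Early S minus Late S relative to the library medians of -1.64 ± 0.0228 and -1.95 ± 0.132 (error from the SDs of both fractions, n = 2 each). The centromeric 1 Mb of 2R was at 0.58 ± 0.260, of 3R at 0.27 ± 0.0612 and of 2L at -0.08 ± 0.141, so an excess of Late S label near the centromere was not shared by all arms. The difference in the telomeric 1 Mb was highest on 3L (1.80 ± 0.227) and 2L (0.89 ± 0.0492), and lower on 3R (0.57 ± 0.0406), 2R (0.39 ± 0.177) and X (0.33 ± 0.0249). These ends were not tested.

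The summed RPKM of the 3 fractions was uneven along the arms. Its median over 117 bins of 1 Mb was 25.3 RPKM, and the lowest bins were X from 12 to 13 Mb with 11.1 ± 0.427 RPKM (SD of the sums by replicate number, n = 2), 3L from 23 to 24 Mb with 11.8 ± 0.517, 2R from 0 to 1 Mb with 12.1 ± 0.00705 and X from 11 to 12 Mb with 15.3 ± 0.198. Those of 3L and 2R lie at the centromeric end of their arm. The bins of 2R from 8 to 9 Mb and from 9 to 10 Mb held 34.2 ± 0.431 and 34.9 ± 0.619, and the first 1 Mb of 2L held 34.0 ± 0.351. Across bins, which are not independent, the sum had a Spearman's rho of 0.201 with timing.

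The tests on Mid S were chosen with the pattern known and before their own values were seen. Windows with the highest mean in Mid S formed 1322 runs on X, 2L, 2R, 3L, 3R and 4, with a median of 5 windows. Of the 1319 runs with a neighbour on both sides, 39.5% lay between an Early S and a Late S run, 30.9% between Early S runs and 29.6% between Late S runs. A mixture of early and late cells in the Mid S gate cannot exceed both other fractions in RPKM. In 834 windows picked in the replicate 1 libraries as at least 25% higher in Mid S than in both others, the median log2 ratio of Mid S to the higher of the others was 0.24 in the replicate 2 libraries, and 0.27 with the numbers exchanged. Sampling noise among interchangeable fractions would leave about a random share of these above both others, but 83.9% were, and 85.4% with the numbers exchanged. The fractions were not interchangeable, since the medians of the Mid S libraries (7.60 and 7.52 RPKM) were the highest. A constant offset of Mid S would also keep many picked windows above both others. This share therefore cannot decide about sampling noise in the choice of windows. Replication in mid S stays open as a hypothesis. Unlabelled DNA or a sequence bias of the Mid S libraries stays open, since neither was tested, and centring the libraries on their medians left 0.13% of windows called.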
